A study of Mus musculus with 16 samples.

How the data were processed

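The libraries measured total RNA of cultured mouse neurons, prepared per the labels with the SMARTer Stranded Total RNA-Seq kit from RNA purified by RNeasy Micro columns. Per the submitters' processing notes, the authors used FastQC, HISAT or HISAT2, featureCounts and DESeq2 with genome build GRCm38; versions, annotation release, strand setting and filters are not stated. The 3 deposited tables, one per peptide, each hold all 16 libraries for 45724 genes. The deposited library values are signal, namely gene counts that the authors divided by 1 size factor per library, with the same values in all 3 tables to within 4.9e-07. Every nonzero value, 100% in each library, was a whole multiple of that library's step at a tolerance of 0.01 reads, so the read counts could be recovered. The deposited tables also give the authors' fold change and its standard error as log2 values, a Wald statistic as a score, and a p-value with its adjusted form, which appear here only where the authors' table is named. Read counts refit by DESeq2 over the 16 libraries gave 425, 272 and 163 genes at an adjusted p under 0.05 for NP24, Tβ10 and Tβ4, where the deposited tables hold 409, 263 and 163.

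Gene positions came from GENCODE M21, in which 45045 of the gene identifiers were found with their version and 45596 without. Of 11 pairs of genes that cover 90% of each other on opposite strands, 9 held read totals within 10% of each other, so reads appear to have been counted without regard to strand, and values of overlapping genes are uncertain. Among genes with over 160 reads in all, 28 had the same 16 counts as another gene. Numbers of genes changed can therefore hold the same reads more than once. Depth was 11642242 to 38254320 reads in genes per library, and 1 read corresponded to 0.536 to 1.71 normalized counts. The lowest chi-square per degree of freedom between libraries of a group was 9.47, so pooled over genes the spread between libraries exceeded counting error. Genes with many reads can dominate this value, so it does not show what sets the precision of genes with few reads.

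Groups were the control, NP24, Tβ10 and Tβ4, with 4 libraries each. The labels do not say whether the replicates are separate cultures, so each p measures spread between these samples, and the replicate numbers are not stated to pair samples across groups. Because the deposited values are normalized, the plan's provision for such values applied: limma-trend (limma 3.58.1 in R 4.3.3) on log2 of the value plus 1, for genes with at least 10 normalized counts in at least 4 of the libraries compared, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each peptide was compared with the control in a fit of their 8 libraries. Peptides were compared with each other in 1 fit of all 16 libraries. The plan had reserved that fit for unnormalized values, and it was used because all 16 columns share 1 normalization; fits of the 8 libraries concerned stand beside it. The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

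Gene lists, 30 in all, covered pathways and markers of neurons and other cell types; 29 had the 5 tested genes required, and the markers of red blood cells did not. They were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera compares the mean test statistic of a list's genes with that of all other genes and uses no ranks. Lists said to rank higher or lower had a mean statistic above or below that of the other genes, which a few large members can drive. Camera with an estimated correlation and fry, a self-contained test of whether a list's genes move on balance in 1 direction, were run beside it. Counts adjusted over the list alone use the p values of the list's own genes. A further set of lists (lysosome, tRNA synthetases of the cytosol, nuclear-retained lncRNAs, olfactory and vomeronasal receptors, and a division of the stress list) was chosen after the data were seen. Those of them tested with camera were adjusted only among themselves, not together with the lists fixed beforehand.

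Genes were named by rule: in each peptide comparison with control, up to 12 per direction with the largest change among genes with adjusted p under 0.05, a mean of at least 50 normalized counts and no overlap between the groups' libraries, leaving out unnamed gene models and pseudogenes. Where fewer than 5 qualified, the 5 with the smallest p per direction were named as not passing. Up to 4 members of each list with the smallest p, and Tmsb4x and Tmsb10, were added, and peptide comparisons with each other used 6 per direction.

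Alternatives were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, scaling to library size or by TMM, other pseudocounts (0.1 and 10), no filter on low values, a fold threshold of 1 on the log2 scale, replicate number as a block, the spread of all 16 libraries, and leaving out each library. Added after the data were seen were TMM, robust moderation, covariates for mitochondrial rRNA share and for the slope of expression on gene-body length (over 12789 protein-coding genes), and the Tβ4 comparisons without libraries 1 and 2. The 35 ways to divide 8 libraries into groups of 4 were each fitted with the same libraries as the comparison itself, so with all 16 between peptides, where the other 8 kept their groups. Shared controls were examined with 100 simulated sets of unchanged groups and with the 6 ways to divide the control libraries. On simulated data with 200 changed genes, limma recovered 38.8%, 76.1% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold in the NP24 comparison, 32.8%, 77.6% and 98.5% for Tβ10 and 10.4%, 53.7% and 92.4% for Tβ4, and false calls made up 2.10%, 4.14% and 3.70% of calls. Plots and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.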

Results

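Primary neurons were cultured from the brains of C57BL/6 mice on postnatal day 0 and received either 1 of 3 peptides attributed in the labels to the subcommissural organ or the vehicle, Dulbecco's phosphate-buffered saline (DPBS). The subcommissural organ is a secretory gland in the roof of the brain's ventricular system that releases its products into the cerebrospinal fluid. The peptides were NP24, Tβ10 and Tβ4 (Tb10 and Tb4 in the plots); the latter pair are β-thymosins, small peptides that bind actin monomers and are encoded in the mouse by Tmsb10 and Tmsb4x. Total RNA was sequenced from 16 libraries, 4 per group. Reads assigned to genes ranged from 11642242 in Tβ10 library 4 to 38254320 in Tβ10 library 1. Between 29325 and 38072 genes were detected per library, the most in Tβ4 library 1. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 11.3 ± 2.07% of reads in controls, 7.15 ± 1.03% with NP24, 7.20 ± 1.96% with Tβ10 and 15.3 ± 6.71% with Tβ4 (mean ± SD, n = 4), and reached 24.3% in Tβ4 library 1. Levels below are normalized counts as mean ± SD of 4 libraries, differences are log2 values ± SE, and adjusted p values are from limma.

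**Figure D1:**
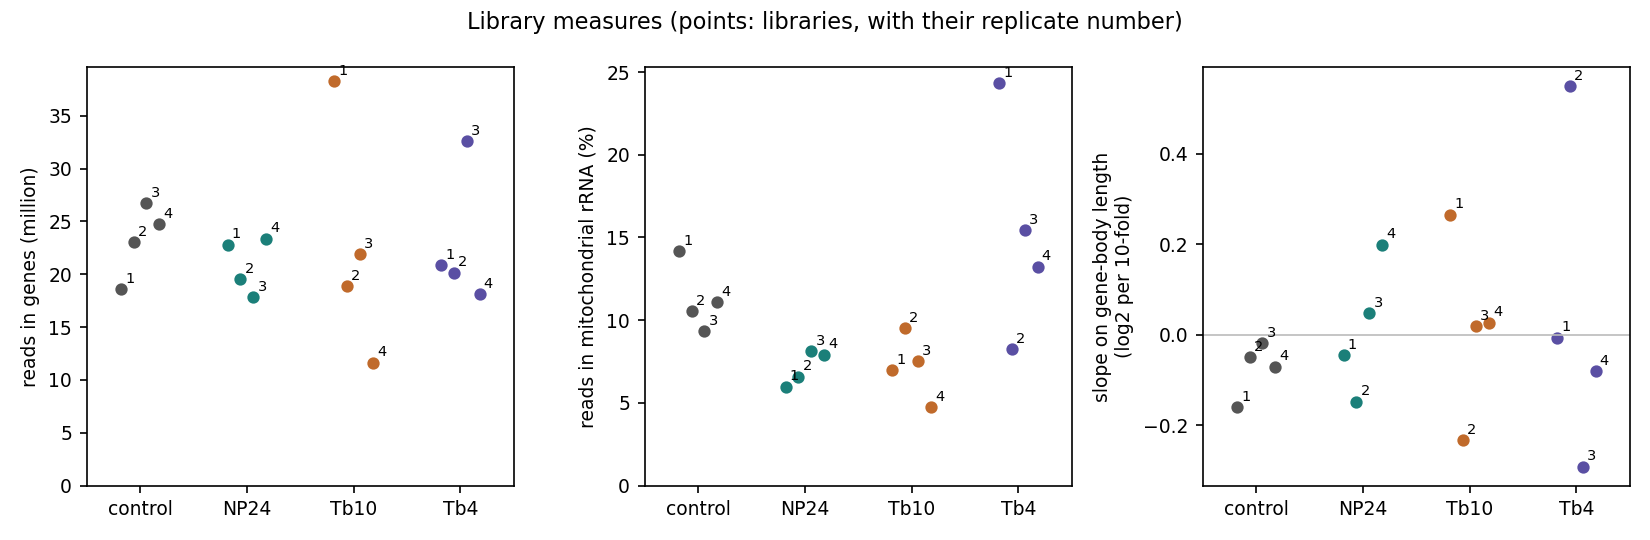
Each point is 1 library, numbered by replicate, in the control, NP24, Tb10 and Tb4 groups. The panels give reads in genes, the percentage of reads in mitochondrial rRNA, and the slope of log2 expression on gene-body length (log2 per 10-fold length). Tb4 library 1 had the highest mitochondrial rRNA percentage, 24.3%, and Tb4 library 2 the highest slope, 0.548.

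The comparison of NP24 with DPBS asked which transcripts differed in neurons that received this peptide. Integrated stress response genes were lower with NP24 in 12 of 24 cases, cholesterol synthesis genes in 7 of 24, fibroblast genes in 4 of 9 and macrophage genes in 4 of 11. The astrocyte water channel gene Aqp4 was among those that rose, though NP24 exceeded Tβ4 for it by only 0.33 (95% interval -0.28 to 0.94). Slc7a11, the transport subunit of the cystine/glutamate exchanger (ENSMUSG00000027737.10, GRCm38 chromosome 3, 49892526 to 50443614, minus strand), fell 4.78-fold, from 1856 ± 581 to 372 ± 23.3 (log2 -2.26 ± 0.17, adjusted p = 1.45e-07). Gpnmb, a transmembrane glycoprotein of lysosomes (ENSMUSG00000029816.10, chromosome 6, 49036546 to 49070929, plus strand), fell 8.81-fold, from 462 ± 110 to 53.2 ± 21.5 (-3.14 ± 0.26, adjusted p = 3.97e-07). Aqp4 (ENSMUSG00000024411.11) rose 3.26-fold, from 125 ± 49.8 to 384 ± 62.4 (1.70 ± 0.25, adjusted p = 0.000934). Ajap1, which encodes a protein of adherens junctions (ENSMUSG00000039546.9, chromosome 4, 153373221 to 153482811, minus strand), rose from 671 ± 71.1 to 1279 ± 169 (0.93 ± 0.12, adjusted p = 0.000297). The share of reads in mitochondrial rRNA was lower with NP24 as well, 7.15% against 11.3%.

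In all, 572 of 21774 genes tested changed with NP24, 253 higher and 319 lower, and 124 of these by more than 2-fold. Among those with all NP24 libraries below all controls, the largest falls beside Gpnmb and Slc7a11 included the collagen genes Col3a1 (ENSMUSG00000026043.18, chromosome 1, 45311538 to 45349706, plus strand; 94.5 ± 35.9 to 9.53 ± 5.87, -3.29), Col1a1 (-2.40) and Col1a2 (-1.92), the proteoglycan gene Bgn (-2.41) and Aebp1 (-2.14). Lyz2, the lysozyme of macrophages, fell by 2.54, the cytokine gene Clcf1 by 2.31, and Trib3, a pseudokinase gene induced by ATF4 (ENSMUSG00000032715.9, chromosome 2, 152337422 to 152344032, minus strand), by 2.20. The glucuronosyltransferase genes Ugt1a6a (-1.90) and Ugt1a6b (-1.84) share exons, so their reads are not separate measurements. Among genes that met the naming rule, which leaves out unnamed gene models and low counts, the largest rises after Aqp4 were in Wif1 (2.64-fold), a secreted Wnt inhibitor, Klhl14 (1.30), Papss2 (1.14), which makes the sulfate donor, the NADPH oxidase gene Nox4 (1.14), Glis1 (1.13) and Dnajc25 (1.08). They were followed by Tspan11 (0.90), Retreg1 (0.89), a receptor for turnover of the endoplasmic reticulum, Arhgap29 (0.89) and Gpr63 (0.88). The transcripts of the thymosins themselves gave values of 0.12 for Tmsb4x (adjusted p = 0.651) and 0.05 for Tmsb10 (adjusted p = 0.895) with NP24. Of the 24 genes chosen for their large change, 12 passed whichever library was left out: Ajap1, Aqp4, Arhgap29, Bgn, Col3a1, Glis1, Gpnmb, Gpr63, Klhl14, Retreg1, Slc7a11 and Trib3. Wif1 passed in 0 of the 8 fits that left out 1 library. Groups of 4 libraries did not overlap in 2142 genes, 9.84% of those tested, where chance gives 2.86%. The count was 106, 243 or 319 without control library 1, 2 or 4 and 292 or 206 without NP24 library 1 or 3. It was 1167 by DESeq2, 120 when the spread came from all 16 libraries, and 0 or 1040 with the mitochondrial rRNA share or the slope on gene length (the length slope) as a covariate, while scaling to library size gave 502 higher and 254 lower. The mitochondrial rRNA share did not overlap between the groups (5.98 to 8.12% against 9.32 to 14.2%), so that covariate cannot be separated from the peptide.

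By list, 12 of 24 measured members of the integrated stress and unfolded protein response fell with NP24 and none rose (13 lower adjusted over the list alone). They included Trib3, the amino acid carrier genes Slc3a2 (2104 ± 252 to 1275 ± 156, -0.72) and Slc7a5 (-0.66), and Sesn2 (-0.89); the list was lower by camera at adjusted p = 1.17e-11, and at adjusted p = 0.161 with an estimated correlation. Of the 20 NRF2 targets, the antioxidant genes, 7 fell (9 adjusted over the list alone), among them Srxn1 (877 ± 192 to 297 ± 24.5, -1.53), Gsta4 (-1.69) and Hmox1 (-1.66). The list passed camera at adjusted p = 1.3e-10, and adjusted p = 0.161 with an estimated correlation. All 24 cholesterol synthesis genes had negative values and 7 fell (12 adjusted over the list alone), such as Lss (2256 ± 400 to 1454 ± 55.7, -0.62), Stard4 (-0.61) and Msmo1 (-0.54). Camera ranked the list at adjusted p = 1.2e-11, and adjusted p = 0.161 with an estimated correlation. Glycolysis and hypoxia genes fell in 4 of 23 cases (5 adjusted over the list alone), with the glucose carrier Slc2a1 at -1.32 and the growth factor Vegfa at -0.86. The list had adjusted p = 0.0028 by camera, and adjusted p = 0.222 with an estimated correlation. Of 25 apoptosis and p53 target genes 3 fell (5 lower and 1 higher adjusted over the list alone), including Cdkn1a (-1.01). As a list they had adjusted p = 0.00414 by camera, and adjusted p = 0.161 with an estimated correlation.

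Immediate early genes, which neurons switch on within minutes of activity, fell in 5 of 20 cases with NP24 (7 lower and 1 higher adjusted over the list alone). Npas4 went from 695 ± 151 to 225 ± 47.5 (-1.62, adjusted p = 2.46e-05) and Egr1 (ENSMUSG00000038418.7, chromosome 18, 34859823 to 34864984, plus strand) from 1802 ± 116 to 662 ± 212 (-1.51, adjusted p = 7.21e-05), and Btg2 was also lower (-0.85). The list passed camera at adjusted p = 4.29e-06, and had adjusted p = 0.222 with an estimated correlation. Targets of the actin-regulated factors SRF and MRTF were lower in 5 of 15 cases (10 adjusted over the list alone), including Acta2 (-3.19), Ccn1 (-1.12), Flna (-0.53) and Srf itself (-0.53); NP24 library 1 stood apart for Acta2, with 46.3 against 5.80 to 7.46 in the others. This list was lower at adjusted p = 7.91e-09 and kept its call with an estimated correlation (adjusted p = 0.0399). The 26 actin regulators themselves held 0 calls by limma, also adjusted over the list alone, with a median of 0.09; camera ranked them higher at adjusted p = 0.0179, and adjusted p = 0.291 with an estimated correlation.

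Markers of other cell types moved with NP24 in both directions. Microglia and macrophage genes fell in 4 of 11 cases (8 adjusted over the list alone), such as Laptm5 (-2.78), Ctss (-2.05) and Cd68 (166 ± 46.9 to 66.3 ± 10.6, -1.28), at adjusted p = 1.55e-07 and, with an estimated correlation, adjusted p = 0.0399. Fibroblast and meningeal genes fell in 4 of 9 cases (4 adjusted over the list alone), the collagens above and Fn1 (-0.49). The list passed camera at adjusted p = 4.65e-06, and adjusted p = 0.138 with an estimated correlation. Rgs5 (-1.68) and Pdgfrb (-0.95) fell among 6 endothelial and pericyte genes (3 adjusted over the list alone; adjusted p = 0.0138, and adjusted p = 0.161 with an estimated correlation). Nes (-0.58), Vim (-0.60) and Tnc (-0.44) fell among 13 radial glia genes (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.00649, and adjusted p = 0.222 with an estimated correlation). Mbp (-0.59) and Olig2 (-0.67) fell among 15 oligodendrocyte lineage genes (4 adjusted over the list alone; adjusted p = 1.71e-05, and adjusted p = 0.222 with an estimated correlation). Of 16 astrocyte genes Aqp4 and the bicarbonate carrier Slc4a4 (0.51) rose (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.0131, and adjusted p = 0.305 with an estimated correlation).

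Genes of cortical projection neurons rose in 4 of 16 cases with NP24 (7 higher and 1 lower adjusted over the list alone): Cux1 (5152 ± 410 to 7167 ± 435, 0.48), Mef2c (0.42), Zbtb18 (0.36) and Bcl11b (0.35). Camera ranked the list at adjusted p = 0.000204, and adjusted p = 0.161 with an estimated correlation. Axon genes were mixed: Basp1 (0.47) and Efnb2 (0.34) rose and the guidance receptor Dcc (-0.50) fell among 34 (10 higher and 3 lower adjusted over the list alone; adjusted p = 0.00649, and adjusted p = 0.222 with an estimated correlation). Among 24 presynaptic vesicle genes Syn1 (2521 ± 133 to 3329 ± 55.5, 0.40) rose (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.00649, and adjusted p = 0.273 with an estimated correlation). Ribosomal protein genes had negative values in 39 of 44 cases, and Rpl13 fell (-0.67; 9 lower adjusted over the list alone; adjusted p = 1.58e-07, and adjusted p = 0.326 with an estimated correlation). Their mean log2 level was lowest in NP24 library 4, at 9.24, which had the group's highest slope on gene length, 0.199. Among 15 mitochondrially encoded genes the rRNA gene mt-Rnr2 fell (-0.74; 4 lower adjusted over the list alone; adjusted p = 0.00304, and adjusted p = 0.427 with an estimated correlation). The other 10 lists tested for NP24 did not pass: excitatory postsynapse (median 0.08), inhibitory neuron (0.08), voltage-gated channels (0.01), neurotrophin signalling (0.12), heat shock (-0.17), nuclear oxidative phosphorylation (0.08), interferon response (median -0.03, mean 0.07), NF-kB (median 0.03, mean -0.01), ependymal and choroid (-0.46) and cell cycle (0.09). The interferon and NF-kB medians change sign with library-size scaling. Of the 19 lists that passed for NP24, only the SRF and microglia lists kept their calls with an estimated correlation.

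**Figure D2:**
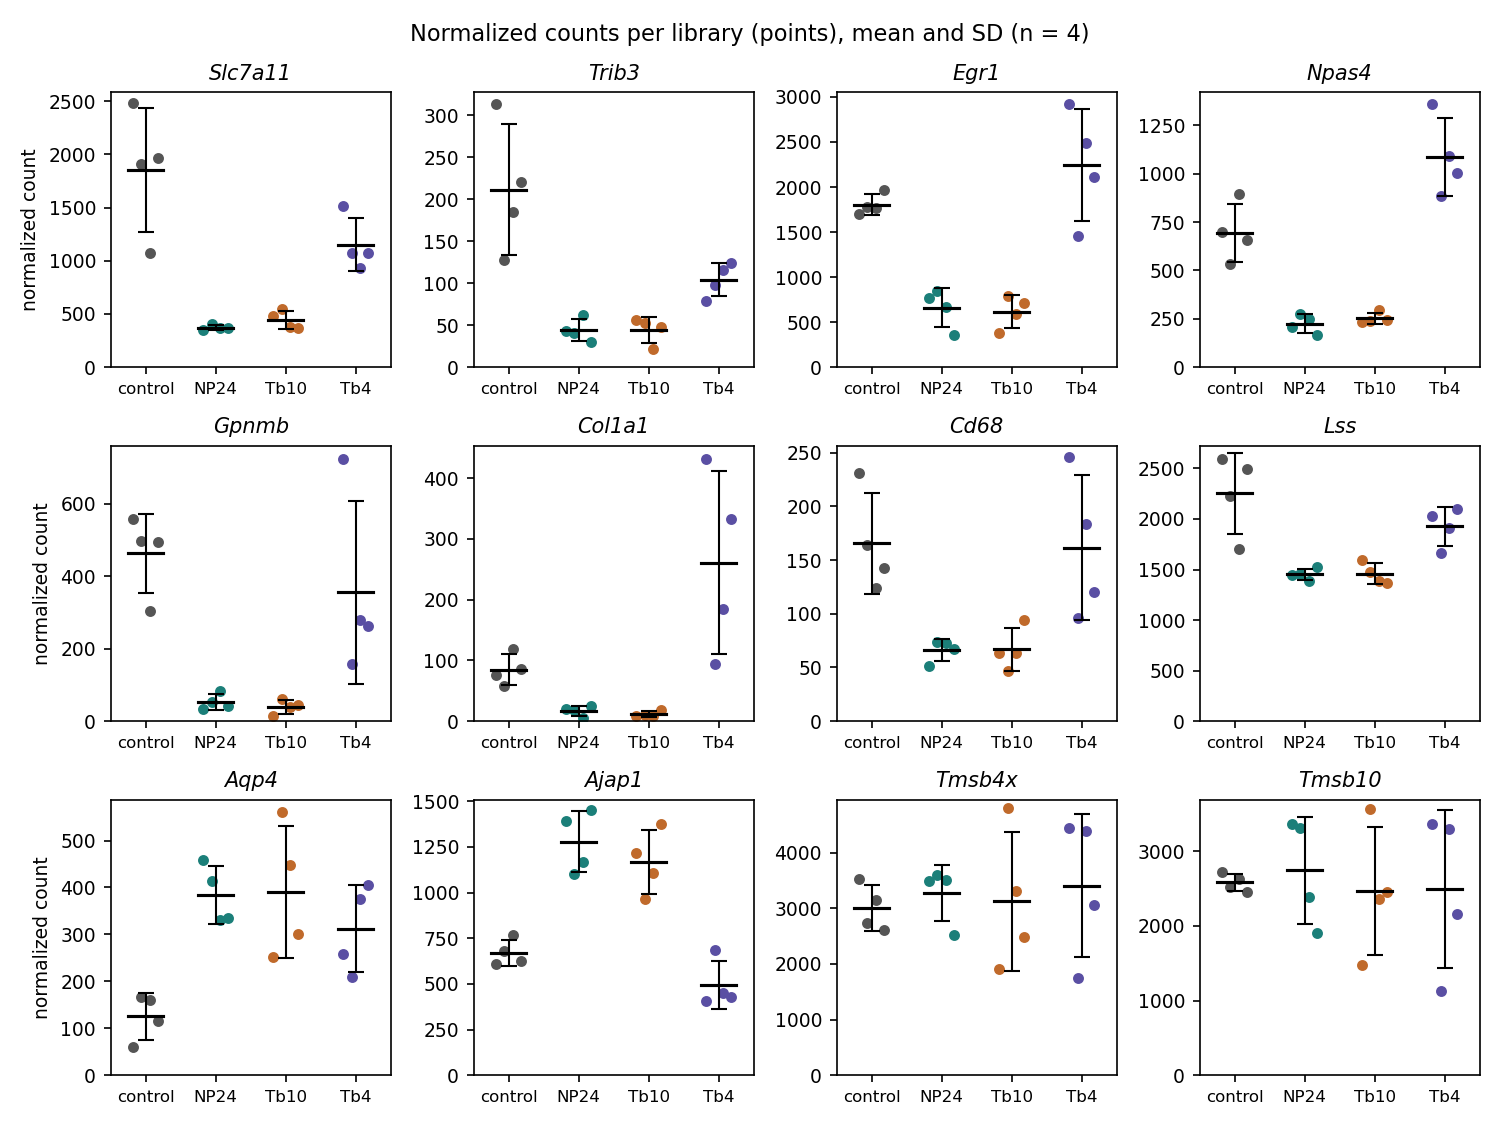
Normalized counts (vertical axis, starting at 0) of 12 genes in each library, by group. Points are libraries and the bars give the mean and SD of 4. Slc7a11, Trib3, Gpnmb and Col1a1 lay lower with NP24 and Tb10 than in controls, while the Tb4 means of Col1a1 (261) and Npas4 (1086) lay above the control means.

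Neurons given Tβ10 differed from the same controls largely through lower transcripts. Gpnmb fell 12.4-fold, from 462 ± 110 to 39.5 ± 18.6 (-3.63 ± 0.33, adjusted p = 4.32e-05), and Slc7a11 4.05-fold, from 1856 ± 581 to 444 ± 83.8 (-2.02 ± 0.20, adjusted p = 7.11e-05). Atf3, a stress-induced transcription factor, fell 5.05-fold, from 111 ± 24.8 to 21.3 ± 5.35 (-2.33 ± 0.33, adjusted p = 0.00178). Aqp4 rose 3.19-fold, to 391 ± 141 (1.67 ± 0.30, adjusted p = 0.01); with Tβ4 it stood at 313 ± 93.3 (1.37 ± 0.32, adjusted p = 0.442), and Tβ4 less Tβ10 was -0.30 (95% interval -0.91 to 0.31). Mitochondrial rRNA took 7.20% of reads with Tβ10 against 11.3% in controls. The transcript of the peptide itself, Tmsb10 (ENSMUSG00000079523.8, chromosome 6, 72957347 to 72958748, minus strand), gave -0.13 ± 0.18 (adjusted p = 0.83). Tmsb4x (ENSMUSG00000049775.16, chromosome X, 167207093 to 167209315, minus strand) gave -0.02 ± 0.20 (adjusted p = 0.984).

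With Tβ10, 139 of 21960 genes changed, 22 higher and 117 lower. The falls again held Col3a1 (-3.43), Lyz2 (-2.75), Aebp1 (-2.49), Trib3 (-2.24), the pericyte gene Rgs5 (-2.21), Col1a2 (-1.91), Hmox1 (-1.99), which degrades heme, Pappa (-1.97), a protease of insulin-like growth factor binding proteins, and Ptgr1 (-1.83). Genes that rose with Tβ10 included the protease inhibitor A2m (2.06), Klhl14 (1.13), Eya4 (0.88), Prss12 (0.84), Necab1 (0.83), Ajap1 (0.79), Frem2 (0.79), Mkx (0.77), Zfp974 (0.75), the hyaluronan-binding Cemip (0.70) and Tcerg1l (0.70). Of the 24 genes chosen for their large change, Atf3, Gpnmb, Hmox1, Pappa, Slc7a11 and Trib3 (6) passed whichever library was left out. Groups did not overlap in 1519 genes, 6.92%, where chance gives 2.86%. The count was 28, 58 or 51 without control library 1, 2 or 4 and 252, 315, 55 or 69 without Tβ10 library 1, 2, 3 or 4. It was 427 by DESeq2, 62 with the spread of all 16 libraries, and 0 or 619 with the mitochondrial rRNA share or the length slope as a covariate, and scaling to library size gave 55 higher and 67 lower. The mitochondrial rRNA share overlapped little between the groups (4.76 to 9.53% against 9.32 to 14.2%), so that covariate is hard to separate from the peptide.

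Integrated stress response genes fell in 8 of 24 cases with Tβ10 (16 adjusted over the list alone), with Sesn2 at -0.96 and Slc3a2 at -0.97 beside Trib3 and Atf3. The list had adjusted p = 7.14e-20 by camera, and adjusted p = 0.17 with an estimated correlation. NRF2 targets fell in 5 of 20 cases (9 adjusted over the list alone), including Gsta4 (-1.82) and Srxn1 (-1.58). As a list they had adjusted p = 1.35e-12 by camera, and adjusted p = 0.175 with an estimated correlation. Cholesterol genes fell in 2 of 24 cases, Lss (-0.61) and Stard4 (-0.70), and 13 did adjusted over the list alone (adjusted p = 1.2e-14, and adjusted p = 0.17 with an estimated correlation). Of 20 immediate early genes 4 fell (11 adjusted over the list alone): Egr1 (1802 ± 116 to 618 ± 181, -1.59), Npas4 (-1.44), Ier2 (-1.43) and Btg2 (-0.98). The list passed camera at adjusted p = 4.46e-11, and adjusted p = 0.175 with an estimated correlation. SRF and MRTF targets fell in 4 of 16 cases (9 adjusted over the list alone), with Acta2 at -2.22 and Ccn2 at -1.91 (adjusted p = 6.29e-10, and adjusted p = 0.085 with an estimated correlation). Apoptosis and p53 targets fell in 3 of 25 cases (5 adjusted over the list alone), including Bbc3 (-1.02; adjusted p = 6.74e-05, and adjusted p = 0.17 with an estimated correlation). Slc2a1 (-1.14) and Vegfa (-0.84) fell among 23 glycolysis and hypoxia genes (4 adjusted over the list alone; adjusted p = 0.00492, and adjusted p = 0.501 with an estimated correlation).

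For other cell types with Tβ10, fibroblast genes fell in 3 of 9 cases (4 adjusted over the list alone), with Col1a1 at -2.81 (adjusted p = 2.15e-07, and adjusted p = 0.148 with an estimated correlation). Cd68 (-1.30) fell among 13 microglia genes (6 adjusted over the list alone; adjusted p = 4.12e-06, and adjusted p = 0.175 with an estimated correlation). Rgs5 and Pdgfrb (-0.97) fell among 7 endothelial and pericyte genes (3 adjusted over the list alone; adjusted p = 0.000882, and adjusted p = 0.17 with an estimated correlation). Nes fell (-0.83) among 13 radial glia genes (3 adjusted over the list alone; adjusted p = 0.0351, and adjusted p = 0.496 with an estimated correlation), a list whose median of -0.07 turned positive with library-size scaling. Aqp4 was the 1 astrocyte gene of 16 that rose (3 adjusted over the list alone; adjusted p = 0.0433, and adjusted p = 0.669 with an estimated correlation). None of the 44 ribosomal protein genes passed by limma, over all genes or adjusted over the list alone (0), although all 44 had negative values, with a median of -0.35 (adjusted p = 1.27e-12, and adjusted p = 0.4 with an estimated correlation). Their mean log2 level was 8.91 in Tβ10 library 1, where the slope on gene length was 0.265, and 9.45 to 9.92 in the other Tβ10 libraries. Heat shock genes ranked lower (median -0.25, 4 adjusted over the list alone, adjusted p = 0.0106, and adjusted p = 0.488 with an estimated correlation). So did oligodendrocyte lineage genes (-0.30, 4 adjusted over the list alone, adjusted p = 0.000149, and adjusted p = 0.344 with an estimated correlation). Mitochondrially encoded genes had a median of -0.16, with 0 passing by limma adjusted over the list alone (adjusted p = 0.0152, and adjusted p = 0.669 with an estimated correlation). Cortical projection neuron genes ranked higher (median 0.10, 3 adjusted over the list alone, adjusted p = 0.00649, and adjusted p = 0.212 with an estimated correlation). Of the 17 lists that passed for Tβ10, 0 did with an estimated correlation, and 5 passed fry, a test of whether the members move 1 way on balance. The voltage-gated channel list, which did not pass, had a median of 0.02 and a mean of -0.01.

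**Figure D3:**
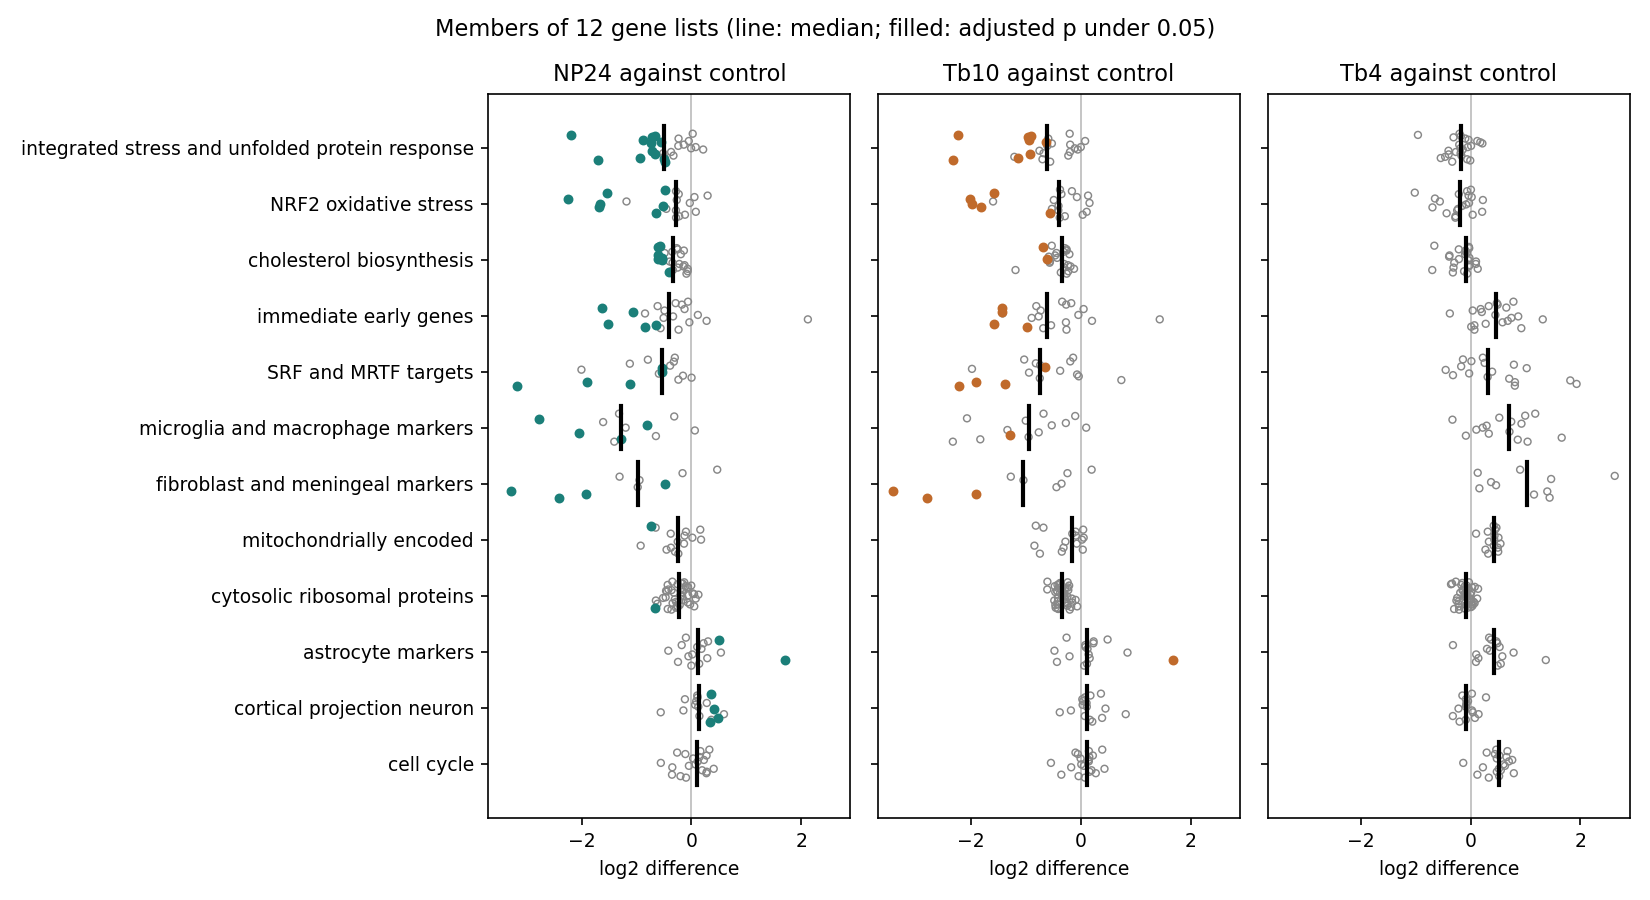
The log2 difference from control (horizontal axis) of each measured member of 12 gene lists, for NP24, Tb10 and Tb4. Lines are list medians and filled points are genes with adjusted p under 0.05. The integrated stress list had medians of -0.50, -0.63 and -0.18, and the cell cycle list 0.09, 0.10 and 0.52.

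Tβ4 gave a different picture from the same controls: by limma 0 of 22205 genes changed, with 1568 at an unadjusted p under 0.05, and edgeR also gave 0, while DESeq2 gave 65 and the authors' deposited table holds 163, 123 higher and 40 lower. The smallest p belonged to Txnip (ENSMUSG00000038393.14, chromosome 3, 96557957 to 96561883, plus strand), which binds thioredoxin and restrains glucose uptake: 486 ± 95.3 with Tβ4 against 181 ± 40 in controls (1.43 ± 0.20, adjusted p = 0.124). A gene model on the opposite strand overlaps Txnip, and the strand setting of the counting is not stated. The authors' DESeq2 values for Txnip were 1.43 with an adjusted p of 8.65e-06. Next came Ccn2 (257 ± 115 against 67.5 ± 12.6, 1.82, adjusted p = 0.375), Rgs5 (1.74), Daam2 (0.88) and the proliferation marker Mki67 (0.65, adjusted p = 0.442) with positive values. The smallest p values among negative differences were those of Kifc2 (-0.74, adjusted p = 0.375), Eps8l1 (-0.95), Plekhn1 (-0.59), Ybx2 (-1.01) and Dennd6b (-0.73). Tmsb4x, which encodes this peptide, gave 0.10 ± 0.25 (adjusted p = 0.974) and Tmsb10 -0.18 ± 0.27 (adjusted p = 0.954). Tβ4 libraries held 15.3 ± 6.71% mitochondrial rRNA, and library 1 held 371 CPM (counts scaled to the library's total) in olfactory and vomeronasal receptor genes, a list added after the data were seen, against 44.8 to 97.5 in the other 15 libraries. Without Tβ4 library 2 the count was 354, and without libraries 1 and 2, chosen after the data were seen, it was 167. In simulated data 53.7% of genes changed 2-fold were recovered with these libraries, against 76.1% and 77.6% in the NP24 and Tβ10 comparisons.

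Gene lists ranked in both directions with Tβ4, and none of their members passed over all genes (0 by limma). Cell cycle genes had positive values in 19 of 20 cases, with a median of 0.52 and 6 higher adjusted over the list alone, such as Top2a (1836 ± 419 against 1135 ± 160, 0.67) and Mcm5 (0.76). Camera gave adjusted p = 3.07e-11, and adjusted p = 0.226 with an estimated correlation. Fibroblast genes were positive in 10 of 10 cases (7 adjusted over the list alone), with Col1a1 at 1.44 and Fn1 at 0.46 (adjusted p = 5.62e-08). Astrocyte genes were positive in 15 of 16 (6 adjusted over the list alone), with Slc1a2 at 0.49 and Slc1a3 at 0.47 (adjusted p = 1.91e-08). The same held for immediate early genes in 19 of 20 (6 adjusted over the list alone), with Nr4a3 at 0.78 and Npas4 at 0.65 (adjusted p = 3.78e-08). Each of these had adjusted p = 0.226 with an estimated correlation. Endothelial and pericyte (median 0.88, 2 adjusted over the list alone), microglia (0.71), ependymal (0.62), mitochondrially encoded (0.43), SRF (0.31, 2 higher and 1 lower adjusted over the list alone) and radial glia genes (0.29) also ranked higher by camera. These had adjusted p = 0.226 (endothelial) to adjusted p = 0.543 (mitochondrially encoded) with an estimated correlation. Lists that ranked lower were presynaptic vesicle (median -0.19, adjusted p = 0.000485, and adjusted p = 0.238 with an estimated correlation), voltage-gated channels (-0.19), excitatory postsynapse (-0.18), inhibitory neuron (-0.17), NRF2 (-0.19, 2 adjusted over the list alone), integrated stress (-0.18) and cholesterol genes (-0.09, 1 adjusted over the list alone). These had adjusted p = 0.226 (inhibitory neuron) to adjusted p = 0.57 (cholesterol) with an estimated correlation, so 0 of the 17 lists passed that way. Slc7a11 had -0.65 ± 0.22 (adjusted p = 0.547) and Trib3 -0.96 ± 0.28 (adjusted p = 0.458). Without Tβ4 library 1 the number of lists fell from 17 to 11. Median and mean differed in sign for glycolysis genes (-0.08 and 0.02), which did not pass.

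NP24 and Tβ10 were then set against each other to ask whether their effects differed. Of the 596 genes changed by either, all 596 had the same sign in both comparisons, a count that the shared controls raise by construction, and 115 passed in both, 18 higher and 97 lower, with 0 in opposite directions. Not all of these are separate measurements: n-R5s193 and Gm47301, for example, had equal values in both comparisons. Tested directly, 0 of 24232 genes differed between NP24 and Tβ10 by limma, 0 of 24266 by edgeR and 0 of 45473 by DESeq2. By limma 591 had an unadjusted p under 0.05, 2.44% of those tested. Over the 596 genes, the median absolute difference was 0.152 with a median 95% half-width of 0.362, and 500 intervals lay wholly within 1 log2 unit of 0; a p that misses the threshold does not show that the peptides act alike. For Slc7a11 the difference was -0.24 (95% interval -0.65 to 0.17), for Gpnmb 0.50 (-0.36 to 1.35), for Egr1 0.08 (-0.42 to 0.59) and for Aqp4 0.03 (-0.58 to 0.64). The smallest p values went to Asf1b (-1.07), Rgs11 (-0.98), Tube1 (-0.73), Slc30a10 (-0.68), Traf6 (-0.48), Pitpnm2os2 (1.29), Slc25a15 (0.77), Dusp4 (0.61), Pdk3 (0.48) and Cfdp1 (0.35), all with adjusted p = 1.00. By camera the integrated stress list (median 0.14, adjusted p = 0.00643), nuclear oxidative phosphorylation (0.14, adjusted p = 0.0141) and presynaptic vesicle genes (0.08, adjusted p = 0.0167) ranked higher with NP24. Each had adjusted p = 0.946 with an estimated correlation and 0 members passing adjusted over the list alone.

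**Figure D4:**
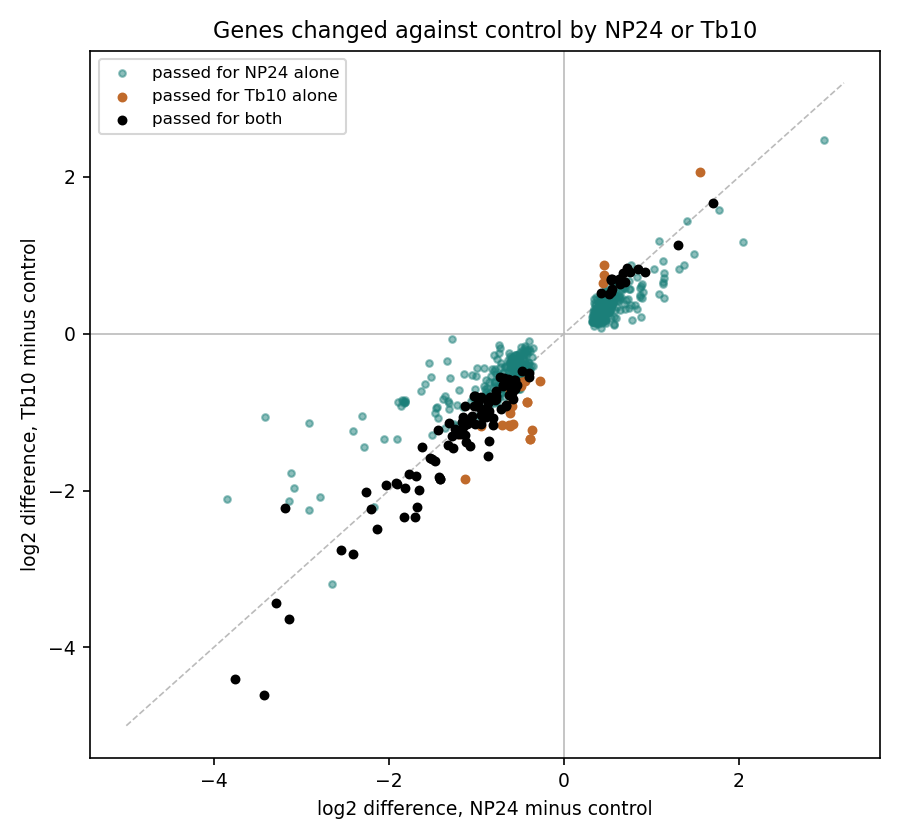
The log2 difference from control with NP24 (horizontal) and Tb10 (vertical) for the 596 genes changed by either; the dashed line marks equal differences. Black points are the 115 genes that passed in both, and all 596 have the same sign on both axes.

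The comparisons of NP24 and Tβ10 with control share the same 4 control libraries, which correlates them by construction. Groups simulated without any effect but with a shared control gave a median correlation across genes of 0.528, against 0.713 observed (genes are not independent replicates). The highest of the 100 draws was 0.838, so the correlation lies within the range that sharing controls gives. The draws gave an overlap of 0 genes in each case. Without any effect few genes can pass, so this count cannot tell how far shared controls raise the overlap. With the controls divided so that each peptide had its own pair, 3 to 10 genes passed in both, with a median of 6. Each fit then held fewer controls, which lowers the number of calls. The correlation across genes was then 0.259 to 0.302. It was -0.0675 to 0.0239 for NP24 and Tβ4 and -0.0491 to 0.0651 for Tβ10 and Tβ4. Part of the correlation between NP24 and Tβ10 thus remained without a shared control library. The 97 genes lower in both were also lower than in Tβ4 libraries, with a median of -0.945 for NP24 and -1.01 for Tβ10, while their median in Tβ4 against control was -0.0743. In the direct tests against Tβ4, 58 and 60 of the 97 passed, and so did 8 and 10 of the 18 higher genes. These genes were chosen for their NP24 and Tβ10 values in the same data, which favours such differences.

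Tβ4 and Tβ10, the related thymosins, differed directly in 326 of 24232 genes, 254 higher and 72 lower with Tβ4. Of the 35 ways to divide these 8 libraries, 3, the real one included, gave at least as many genes (highest other 2289). Chance can therefore not be excluded for this count. The collagen gene Col3a1 stood at 267 ± 148 with Tβ4 against 10.3 ± 8.73 with Tβ10 (4.83 ± 0.59, adjusted p = 0.000218). Col1a1 (4.25), Rgs5 (3.95), Ccn2 (3.73) and Col1a2 (3.06) were also higher with Tβ4, and the kinase gene Dclk3 (-1.34), Ajap1 (-1.26), Sla (-1.20), Tg (-1.13), Rxrg (-1.04) and Mkx (-1.03) were lower. Of these, Mkx did not pass without Tβ4 library 1 or in the fit of 8 libraries (adjusted p up to 0.0732), nor Rxrg in the latter (adjusted p = 0.0966). The others passed whichever library was left out. Whether the similar values of Sla and Tg are separate measurements was not tested. Immediate early genes were higher with Tβ4 in 8 of 20 cases (16 adjusted over the list alone), with Npas4 at 2.09 (adjusted p = 2.15e-06) and Egr1 at 1.87. SRF targets were higher in 5 of 17 (11 higher and 1 lower adjusted over the list alone), microglia genes in 7 of 16 (12 adjusted over the list alone) and fibroblast genes in 6 of 11 (8 adjusted over the list alone). With an estimated correlation the SRF (adjusted p = 0.00354), fibroblast (adjusted p = 0.0141), immediate early, microglia and endothelial lists (each adjusted p = 0.0234) stayed higher and cortical projection genes (adjusted p = 0.0458) stayed lower. Mitochondrial rRNA took 15.3% of reads with Tβ4 and 7.20% with Tβ10, so this share as a covariate is partly confounded with the peptides. The count was 172 or 171 without Tβ10 library 3 or 4 and 87, 1052 or 145 without Tβ4 library 1, 2 or 4. It was 77 when only these 8 libraries were fitted, 799 by DESeq2, and 10 or 1467 with the mitochondrial rRNA share or the length slope as a covariate; library-size scaling, under which the median of all genes lay at -0.180, gave 164 higher and 443 lower.

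NP24 against Tβ4 gave 507 genes, 107 higher and 400 lower with NP24, of the same kinds. At least as many came from 2 of the 35 ways to divide these 8 libraries, the real one included (highest other 639). Chance can therefore not be excluded here either. Col3a1 (-4.68), the smooth muscle actin gene Acta2 (-3.99), Bgn (-3.91), Col1a1 (-3.84) and Ccn2 (-3.72) were lower with NP24. Ajap1 (494 ± 130 with Tβ4 against 1279 ± 169, 1.39 ± 0.16, adjusted p = 0.000158), Dclk3 (1.33), Sla (1.12), Tg (1.06), Klhl14 (0.99) and Maf (0.95) were higher. Of these, Klhl14 did not pass without NP24 library 1, 3 or 4 or Tβ4 library 1 or 4 (adjusted p up to 0.123), and the others passed whichever library was left out. Sla and Tg again had similar values, and whether their reads are separate was not tested. Microglia genes fell in 7 of 16 cases (12 adjusted over the list alone), fibroblast genes in 6 of 11 (7 adjusted over the list alone). Immediate early genes fell in 6 of 20 (12 adjusted over the list alone) and SRF targets in 4 of 17 (10 lower and 1 higher adjusted over the list alone). Presynaptic vesicle genes rose in 2 of 24 cases (8 adjusted over the list alone), with a median of 0.30. With an estimated correlation the SRF (adjusted p = 0.00463), microglia and fibroblast (each 0.0176), endothelial (0.031) and immediate early lists (0.0486) stayed lower, and presynaptic and inhibitory neuron (each 0.0185), cortical projection (0.031) and axon genes (0.0486) stayed higher. The share of reads in mitochondrial rRNA was 7.15% with NP24 and 15.3% with Tβ4, so as a covariate it is partly confounded with the peptides. The count was 286, 290 or 296 without NP24 library 1, 3 or 4 and 104, 1392 or 266 without Tβ4 library 1, 2 or 4. It was 109 when only these 8 libraries were fitted, 1212 by DESeq2, and 7 or 1946 with the mitochondrial rRNA share or the length slope as a covariate; library-size scaling, under which the median of all genes lay at 0.133, gave 362 higher and 269 lower. In the comparisons between peptides, median, mean and test differed in sign for the neurotrophin and heat shock lists (NP24 against Tβ4), the neurotrophin and actin lists (Tβ4 against Tβ10), and the SRF, channel, mitochondrial, interferon, endothelial and fibroblast lists (NP24 against Tβ10), none of which passed.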

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

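The values here met a gap test fixed before the data were examined: the highest or lowest of 4 libraries lay far from the nearest other relative to the group's range (a ratio above 0.829). It was met in 15 of the 292 groups of 4 tested, and chance alone marks about 1 in 20 groups. None of the 7 measures of whole libraries tested, such as depth or mitochondrial rRNA share, met it. Other library measures were not put to this test. Among them, reads of olfactory and vomeronasal receptor genes stood at 371 CPM in Tβ4 library 1, against 57.5 to 59.1 in the other Tβ4 libraries.

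Tβ4 library 2 had 688 normalized counts of Ajap1 where the other Tβ4 libraries had 408 to 449. The same library had 869 of Retreg1 against 440 to 510. For A2m it had 60.2 against 86.4 to 91.7, and for Pdk3 481 against 362 to 380. In Tβ4 library 3, Daam2 stood at 401 against 505 to 523 and Sla at 839 against 575 to 584.

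Among NP24 libraries, library 2 had 110 of Atf3 where the others had 19.7 to 25.9, 1034 of Kifc2 against 508 to 563, and 248 of Rxrg against 213 to 217. NP24 library 1 had 46.3 of Acta2 against 5.80 to 7.46 and 1220 of Tg against 1518 to 1563. NP24 library 4 had 2519 of Tmsb4x against 3485 to 3603.

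Tβ10 library 4 had 396 of Dclk3 against 344 to 349, and Tβ10 library 1 had 1551 of Cfdp1 against 1784 to 1810. Control library 3 had 45.9 of Clcf1 where the other controls had 109 to 117.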

How the results depend on the processing

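Chosen after the data were seen were TMM scaling, robust moderation, both covariates, DESeq2 over 16 libraries and the fits without Tβ4 libraries 1 and 2. The cause of the differences below was not tested, except that a fold threshold leaves fewer calls by construction. Genes named for NP24 gave 3097 results under alternatives, of which 2656 kept their side of the threshold, 370 lost it and 71 gained it. For Tβ10 these were 3047, 2701, 276 and 70, for Tβ4 3281, 3159, 0 and 122, for Tβ4 against Tβ10 317, 306, 11 and 0, for NP24 against Tβ4 317, 299, 18 and 0, and for NP24 against Tβ10 all 261 stayed. None reversed (0).

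DESeq2 on recovered reads gave 1167 genes for NP24, 427 for Tβ10, 65 for Tβ4, 799 for Tβ4 against Tβ10 and 1212 for NP24 against Tβ4, and overlaps of 286 (NP24 and Tβ10), 12 (NP24 and Tβ4) and 4 (Tβ10 and Tβ4). DESeq2 over all 16 libraries gave 272 for Tβ10 and 163 for Tβ4, or 18 for Tβ4 without library 1. The fold threshold gave 124, 68, 168 and 262 for NP24, Tβ10, Tβ4 against Tβ10 and NP24 against Tβ4. Without the filter, NP24 gave 365 and Tβ4 against Tβ10 184. The spread of all 16 libraries gave 120 for NP24, 62 for Tβ10 and 2 for Tβ4, or 3 without Tβ4 libraries 1 and 2, whose omission from the 8-library fit gave 167. Fits of 8 libraries gave 77 for Tβ4 against Tβ10 and 109 for NP24 against Tβ4. Library-size scaling gave 607 for Tβ4 against Tβ10. With the length slope as covariate the counts were 1040, 619, 199, 1467 and 1946 for NP24, Tβ10, Tβ4, Tβ4 against Tβ10 and NP24 against Tβ4, and with the mitochondrial rRNA share 0 for NP24, 0 for Tβ10, 10 for Tβ4 against Tβ10 and 7 for NP24 against Tβ4. The mean mitochondrial rRNA share was lower with NP24 and Tβ10 than in the controls and with Tβ4. As a covariate it is therefore confounded with the peptides, and the low counts do not show that it causes the differences. Divided controls gave an overlap of 6.

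The replicate numbers did not pair the samples: over 24 correlations of residuals between libraries of the same number the range was -0.302 to 0.113. With the number as a block the counts were 477 for NP24, 91 for Tβ10, 2 for Tβ4, 214 for Tβ4 against Tβ10 and 341 for NP24 against Tβ4, with an overlap of 78.

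Lists called numbered 2 for NP24, 0 for Tβ10 and 0 for Tβ4 with an estimated correlation, and 10, 5 and 0 by fry. Leaving out 1 library at a time gave 106 to 760 genes for NP24, 28 to 315 for Tβ10, 0 to 354 for Tβ4, 87 to 1052 for Tβ4 against Tβ10, 104 to 1392 for NP24 against Tβ4 and 0 to 0 for NP24 against Tβ10. The lists numbered 17 to 21, 14 to 18 and 11 to 22 for NP24, Tβ10 and Tβ4. Depth limits genes near the filter most in Tβ10 library 4, where 1 read equals 1.71 normalized counts, against 0.536 in Tβ10 library 1.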

Other observations

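Tests chosen only after their results were seen were the comparison with Tβ4 for shared controls, the search for a batch, the length slope as covariate, all counts of splits, and the lists of this part, which were added after the data were examined. Lysosome genes, which were not among the lists fixed beforehand, fell in 6 of 30 cases with NP24 and 3 of 30 with Tβ10, and 0 of 30 passed with Tβ4 by limma. The aspartic protease gene Ctsd fell by 1.15 on the log2 scale with NP24 (1684 ± 402 to 757 ± 142, adjusted p = 0.000318). The list was lower at adjusted p = 9.12e-09 with NP24, and at adjusted p = 0.0421 with an estimated correlation (unadjusted camera p = 0.00899). Adjustment here spans only the few lists added after the data were seen, so this call does not account for the lists fixed beforehand. With Tβ10 it was lower at adjusted p = 1.67e-10, a call lost at adjusted p = 0.0672 with an estimated correlation. Microglia and macrophage markers were also lower with both peptides by camera, and whether the lysosome genes fell apart from them was not tested. Within the stress list, divided after the data were seen, 11 of the 15 ATF4 and amino acid members passed with NP24 (median -0.66) and 8 with Tβ10 (-0.91). Of the 9 endoplasmic reticulum members, 1 passed with NP24 (median -0.05) and 0 with Tβ10 by limma (-0.20, lower by camera at adjusted p = 0.0397, a call lost at adjusted p = 0.499 with an estimated correlation). The difference between the parts was not tested. Cytosolic tRNA synthetases held 0 calls of 17 by limma in either comparison, with medians of -0.114 for NP24 (camera adjusted p = 0.0915) and -0.200 for Tβ10. The latter was lower by camera at adjusted p = 0.000687, a call lost at adjusted p = 0.315 with an estimated correlation. The nuclear lncRNA Neat1 fell with both peptides (-0.95 and -1.03). Of 10 nuclear-retained lncRNAs, 1 rose and 2 fell with NP24, and 1 fell with Tβ10. Camera gave adjusted p = 0.0328 for NP24, a call lost at adjusted p = 0.439 with an estimated correlation, and adjusted p = 0.825 for Tβ10.

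Transcripts of Y-linked genes were present in all 16 libraries, for example Kdm5d at 598 to 1107 and Ddx3y at 554 to 934 normalized counts, while Xist ranged from 0 to 23.1.

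NP24 and Tβ10 changed 115 of the same genes. For the genes lower in both, the median NP24 difference from the Tβ4 libraries was -0.945 (quartiles -1.61 and -0.491). They were chosen for low NP24 and Tβ10 values, which favours such a difference, so it cannot decide whether shared control libraries gave the pattern. With no control library shared, the differences of the 2 peptides still correlated at 0.259 to 0.302 across genes. That argues against shared controls as the only source of the correlation. A smaller number of microglia and fibroblasts stays open: their marker transcripts fell by 1539 normalized counts with NP24 while 13 stress genes fell by 5921, a ratio of 0.260 (0.150 to 0.494 with its spread) that lies between the bounds set for and against it, and 0.177 (0.0424 to 0.458) with Tβ10, whose spread reaches past the bound set against it. A batch that sets NP24 and Tβ10 apart also cannot be told apart from the peptides. Of the labels, 0 name a batch, but the codes in the sample titles use another letter for controls and run on in order from NP24 to Tβ10 to Tβ4, so a batch that follows them would coincide with the groups. An effect of the peptides on these genes may account for the pattern too and was not tested against these values.

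Calls for Tβ4 depended on the method and the libraries used, from 0 by limma to 163 by DESeq2 over 16 libraries and 354 by limma without Tβ4 library 2. Without Tβ4 library 1, 11 of the 123 higher genes in the authors' table passed in the 16-library DESeq2 fit, and 5 of the 40 lower ones; that library was the highest of 16 for 85 of the 123 (69.1%). It also held 371 CPM in olfactory and vomeronasal receptor genes, against 44.8 to 97.5 in the other 15 libraries. With the slope on gene-body length as a covariate 199 genes passed. Both are consistent with differences among the Tβ4 libraries, in library 1 for the deposited calls and in the slope for the spread, and a Tβ4 effect stays open as untested.

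Libraries differed in the slope of expression on gene-body length, from -0.292 to 0.548, both in the Tβ4 group. Within groups the slope correlated with the level of nuclear-retained lncRNAs (r = 0.867, rho = 0.685, permutation p = 0.00248, adjusted p = 0.00496 over 4 relations; 0.718 without the 2 farthest libraries), so a share of nuclear RNA that differs between libraries may account for it. Ribosomal protein transcripts went the other way (r = -0.944). Their genes belong to the protein-coding genes over which the slope was fitted, so this relation is partly built in. Reads of olfactory and vomeronasal receptors, a proxy for genomic DNA, gave r = 0.0378 (rho = 0.244, permutation p = 0.924), and 0.207 without the 2 farthest libraries, which is too imprecise over 16 libraries to exclude that source; the 371 CPM in these genes of Tβ4 library 1 stand apart at a slope of -0.00676. The mitochondrial rRNA share gave r = -0.462 (permutation p = 0.370).

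Of the 35 ways to divide each set of 8 libraries, only the real division gave as many genes for NP24 (572, highest other 2). The same held for Tβ10 (139, highest other 5). Each is a share of 0.0286, the smallest that 35 divisions can give, not adjusted over the comparisons. The share assumes independent libraries, which the labels do not state, and both comparisons use the same controls. Between peptides, the real and the other divisions were all fitted with 16 libraries, of which the 8 outside the comparison kept their groups. As many genes as the real division gave came from 3 divisions for Tβ4 against Tβ10 (326, highest other 2289). For NP24 against Tβ4 2 divisions did so (507, highest other 639), so chance cannot be excluded for either. For Tβ4 (highest other 2) and NP24 against Tβ10 (highest other 0) the real count was 0, which all 35 divisions reach by definition, so the count of divisions decides nothing. The division with 2289 genes set Tβ10 library 2 and Tβ4 libraries 1, 3 and 4 against the rest, several times the real count, which points to a structure of the samples other than the groups. This division also sorts the libraries by their slope on gene-body length. The slopes were -0.292 to -0.00676 on its first side and 0.0186 to 0.548 in the rest.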
